A study of Arabidopsis thaliana with 15 samples.

How the data were processed

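Messenger RNA from roots of Arabidopsis thaliana was sequenced in 15 samples. The samples came from wild type Col-0 and from gl2-5, a mutant in the gene of the homeodomain transcription factor GLABRA2 (GL2), each in a mock group and an arsenic group. The labels give 9 days of growth on plates with 0.5-strength MS medium, then 1.5 h in liquid medium with 60 µM arsenic, and 30 seedlings per sample. The growth and treatment protocols name As(III), whereas the treatment field of the arsenic samples and the series description name As(V); the form is therefore written here as arsenic. The series description also states 2 replicates and 3 time points, whereas the samples form 4 groups of 3 or 4 replicates at a single time point. Libraries were made with a stranded TruSeq kit and sequenced as 50 bp single-end reads, per the protocols in the labels.

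The deposited files hold raw counts of reads per gene locus, 1 file per library. Per the submitters' processing notes, Trim Galore, STAR 2.5.4, HTSeq 0.6.0 and edgeR were used with the TAIR10 genome; the notes used here do not give the counting mode, the strand setting or the annotation version. Each file has the same 28775 loci, of which 28009 have a row in the reference annotation (TAIR10.1). All 279 organelle loci hold 0 counts in every library. Between 1 and 6 blank lines at the end of each file name no locus and were dropped. Whole-number values and totals that differ between libraries were checked before use. Library totals ran from 13766188 to 29183296 counts. A gene with 0 counts in a library could be present at up to 0.114 to 0.200 CPM (defined with the scaling of libraries), depending on the library, taking 3 counts as the upper limit for counting error only; reads carry no molecular identifiers.

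Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by the filterByExpr function of edgeR with the 4 groups as its grouping, which left 20188 genes and at least 99.956% of the counts of each library. Libraries were scaled by the trimmed mean of M values (TMM). Levels are given as CPM, the count of a gene relative to the TMM-scaled total of its library as returned by the cpm function of edgeR, with the mean and SD over replicates. A quasi-likelihood model with the 4 groups was fitted to all 15 samples, and 5 contrasts were tested: arsenic against mock in wild type, arsenic against mock in gl2-5, gl2-5 against wild type in mock, gl2-5 against wild type in arsenic, and the difference between the arsenic responses of the genotypes (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its contrast. Adjusted p values of genes are from edgeR, two-sided, unless another tool is named. Fold changes are log2 values with an approximate standard error (SE). It is the size of the fold change divided by the square root of the F statistic of its test. The common biological coefficient of variation was 13.5%.

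The groups compared, the contrasts, the alternatives, the rule for the genes that are named, and 27 gene lists with 567 entries were fixed before the data were examined. The lists, written from general knowledge of the genes, were heat shock and folding, phosphate starvation, arsenic transport and chelation, sulfur assimilation and glutathione, detoxification and oxidative stress, root hair cell, epidermal patterning regulators, jasmonate, ethylene, abscisic acid and dehydration, iron deficiency, auxin response, cytokinin response, nitrate response, cell cycle, ribosome biogenesis, unfolded protein response, proteasome, early stress and touch response, aquaporins, hypoxia, sugar starvation, circadian clock, and marker lists for endodermis and suberin, vascular tissue, root meristem and cap, and green shoot tissue. Of the entries, 542 passed the count filter. Each list was tested against all other genes with camera in limma 3.58.1 at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 135 tests of 27 lists in 5 contrasts. The same test with a correlation estimated from the data was run as an alternative. Counts of list members are given over all genes and, where they differ, adjusted over the list alone.

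The genes named are GL2, the genes with the largest rises and falls of each contrast, and up to 4 members of each list with the smallest p. The genes of the largest changes had a call, a mean of at least 1 log2 CPM, no overlap between the replicates of the groups compared, and a symbol of their own, and were taken from the top. No gene of the interaction passed the threshold, so the 5 with the smallest p are given as values without a call. Symbols follow the annotation, which gives 8738 of the tested genes a symbol of their own.

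The tests were tried on simulated counts with the dispersions of these data, in which 200 genes were changed 1.5-fold, 2-fold or 4-fold. The edgeR test recovered 62.7%, 95.5% and 100% of these for arsenic in wild type, 61.2%, 95.5% and 100% for arsenic in gl2-5, 56.7%, 88.1% and 98.5% for the genotypes in mock, 64.2%, 82.1% and 100% for the genotypes in arsenic, and 28.4%, 68.7% and 98.5% for the interaction. False calls by edgeR were 5 of 177, 10 of 181, 12 of 174, 2 of 166 and 8 of 138 calls, in the same order. DESeq2 made 28, 36, 34, 16 and 26 false calls on the same data. For the interaction it recovered 43.3%, 79.1% and 100% of the changed genes, more than edgeR. The dispersions of the simulation were those estimated by edgeR. The changed genes were drawn from those with a mean over 1 log2 CPM, and all other genes had the same mean in every group. In the real arsenic contrasts 64.4% of genes were called in wild type and 64.5% in gl2-5. The simulation therefore does not show recovery or false calls where most genes change, or recovery for genes of lower level. In each of the 5 contrasts camera found the list that had been moved and called 0 of 20 unmoved lists. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera makes false calls for lists whose members vary together.

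Alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, relative log expression (RLE) or upper-quartile scaling in place of TMM, no count filter or a stricter filter of at least 1 CPM in at least 3 samples, counts thinned to the smallest library, a test against a 1.5-fold change, a fit to only the groups compared, the replicate number as a block in all groups, and a fit without each library in turn. Scaling by library totals alone, fits without the 2 or the 4 libraries with the highest green shoot markers, the level of these markers as a covariate, and the replicate number as a block in the 2 arsenic groups alone were added after the data had been seen. Replicate numbers are those of the sample titles, and the labels do not say what they mark. Whether they pair libraries was checked by the correlation of deviations from the group means: all 4 same-number pairs of wild-type and gl2-5 arsenic libraries had r of 0.177 to 0.370, so these 2 groups were taken as paired, from the data and not from the labels. In each of the other 5 pairs of groups at least 1 same-number pair lay below 0.1. Other splits of the samples into groups of the same sizes were fitted in the same way for each comparison. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.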

Results

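Counts of messenger RNA reads per gene were available for roots of wild type Arabidopsis (Col-0) and of the mutant gl2-5, each after mock or arsenic treatment for 1.5 h. The groups held 4 wild-type mock, 4 wild-type arsenic, 3 gl2-5 mock and 4 gl2-5 arsenic libraries, with 13766188 to 29183296 counts each. Replicates of a group correlated across genes at Pearson r of 0.976 to 0.991. The first principal component held 76.9% of the variance. The labels do not say whether replicates were separate cultures, so the p values measure the spread between these samples. The title of the series asks how GL2 links arsenic tolerance with the differentiation of epidermal cells, and the comparisons address what arsenic changed in each genotype, how the genotypes differed, and whether their arsenic responses differed.

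GL2 (AT1G79840, chromosome 1, 30036956 to 30041440, plus strand, TAIR10.1), which encodes a homeodomain transcription factor that represses hair fate in non-hair root cells, served as a check of the labels. Its level was 10.3 ± 0.3004 CPM in wild-type mock (SD, n = 4), 3.43 ± 0.507 in wild-type arsenic (n = 4), 1.01 ± 0.354 in gl2-5 mock (n = 3) and 0.279 ± 0.144 in gl2-5 arsenic (n = 4). Every gl2-5 library lay below every wild-type library. The fall in gl2-5 was −3.34 ± 0.24 in mock (log2, SE, edgeR adjusted p 8.30e-07) and −3.52 ± 0.27 in arsenic (adjusted p 2.15e-06). The gl2-5 arsenic libraries held 3 to 12 reads of the gene each.

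**Figure D1:**
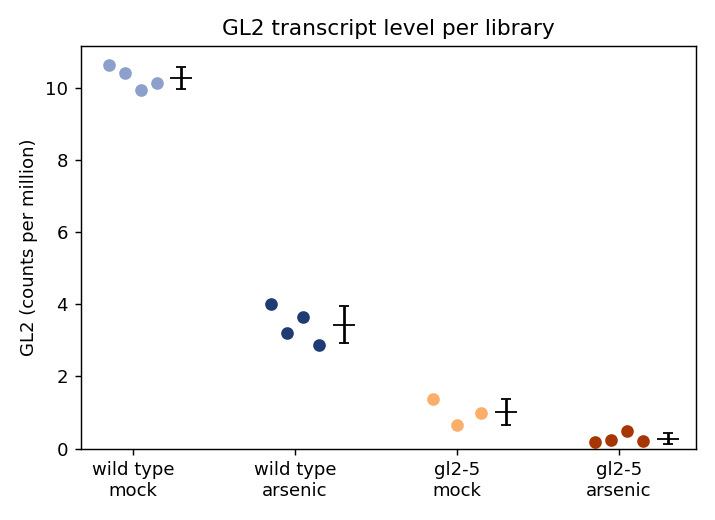
GL2 level in CPM for each library (points) with the mean and SD of each group (bars). Wild-type mock libraries lie at 9.94 to 10.6 and gl2-5 libraries at 0.175 to 1.37.

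Arsenic in wild type raised genes for protein folding, sulfur assimilation, glutathione-linked detoxification and early stress signalling, and lowered genes of root hairs, the endodermis and cytokinin response. All 30 measured heat shock genes rose, with a median of 5.64 log2 units: the small heat shock protein genes ATHSP22.0 (AT4G10250) and HSP18.2 (AT5G59720) rose by 8.30 ± 0.38 and 7.44 ± 0.27, the heat shock factor gene HSFA2 (AT2G26150) by 5.68 ± 0.11 and the chaperone genes HSP70 (AT3G12580) and Fes1A (AT3G09350) by 4.68 ± 0.10 and 5.61 ± 0.11 (SE, n = 4 and 4 libraries). HSFA2 rose from 19.7 ± 2.19 to 1007 ± 75.2 CPM (SD, edgeR adjusted p 1.05e-15). Among the largest rises were also BGLU28 (AT2G44460), a beta-glucosidase gene of sulfur limitation, at 9.34 ± 0.40, the ascorbate peroxidase gene APX2 (AT3G09640) at 8.76 ± 0.27, and the receptor-like kinase gene CRK39 (AT4G04540) at 8.46 ± 0.37. Mock levels of BGLU28 and CRK39 were 0.205 and 0.0806 CPM, so their folds rest on few mock reads.

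Sulfur assimilation and glutathione genes rose in 21 of 26 cases with a median of 1.79 and none fell with TMM scaling. LSU1 (AT3G49580), a marker of low sulfur, rose by 5.62 ± 0.23, the serine hydroxymethyltransferase gene SHM7 (AT1G36370) by 4.30 ± 0.14, the ATP sulfurylase gene APS3 (AT4G14680) by 3.91 ± 0.14 and the APS reductase gene APR3 (AT4G21990) by 3.42 ± 0.13. Detoxification genes rose in 34 of 37 cases (median 2.70), among them the glutathione transferase gene GSTU10 (AT1G74590) by 3.995 ± 0.14 and the oxophytodienoate reductase gene OPR1 (AT1G76680) by 3.72 ± 0.14. In the arsenic transport and chelation list 8 genes rose and 3 fell of 13: the vacuolar phytochelatin transporters ABCC2 (AT2G34660) and ABCC1 (AT1G30400) rose by 2.79 ± 0.09 and 1.59 ± 0.11, the phytochelatin synthase gene CAD1 (AT5G44070) by 2.32 ± 0.13, and WRKY6 (AT1G62300), a transcription factor of arsenate response, by 3.09 ± 0.12. Early stress and touch genes rose in 24 of 29 cases (median 1.74), with WRKY33 (AT2G38470) up by 3.59 ± 0.15 and the camalexin pathway gene CYP71A12 (AT2G30750) by 6.55 ± 0.24. Proteasome genes rose in 26 of 27 cases by a smaller median of 0.66 (27 when adjusted over the list alone), with the lid subunit gene ATS9 (AT1G29150) up by 2.01 ± 0.09 and the segregase gene CDC48 (AT3G09840) by 1.63 ± 0.10.

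Root hair genes fell in 30 of 38 cases and rose in 6, with a median of −1.85. The hair regulator RSL4 (AT1G27740) changed by −3.17 ± 0.18, the expansin gene EXPA7 (AT1G12560) by −2.74 ± 0.18, SHV2 (AT5G49270), a COBRA-like wall gene, by −3.49 ± 0.23 and the peroxidase gene RHS18 (AT5G22410) by −3.36 ± 0.22. Among the largest falls were the arabinogalactan gene FLA6 (AT2G20520) at −5.23 ± 0.39, PRP1 (AT1G54970) at −4.91 ± 0.34 and XTH13 (AT5G57540) at −4.71 ± 0.29, beside the cytochrome P450 gene CYP718 (AT2G42850) at −6.68 ± 0.26 and DXPS1 (AT3G21500) at −4.98 ± 0.43. Of 15 measured epidermal patterning regulators, 9 fell and 3 rose, a list not called against other genes (adjusted p 0.240). GL2 itself fell by 1.58 on the log2 scale, ATMYC1 (AT4G00480) by 1.75 and EGL3 (AT1G63650), both basic helix-loop-helix genes of the same pathway, by 1.18. Endodermis and suberin markers fell in 9 of 13 cases (median −1.43), with the Casparian strip genes CASP4 (AT5G06200) at −3.48 ± 0.28 and PER64 (AT5G42180) at −2.29 ± 0.13 and the regulator SCR (AT3G54220) at −1.28 ± 0.12. Its suberin genes GPAT5, FAR4 and RWP1 lay at 10.3 ± 1.63, 20.9 ± 2.56 and 50.3 ± 6.20 CPM in wild-type mock (SD). In wild-type arsenic they lay at 11.1 ± 1.58, 21.8 ± 3.67 and 42.5 ± 8.74 CPM. The falls of the list therefore do not stand for its suberin genes. Cytokinin response regulators fell in 6 of 10 cases, with ARR3 (AT1G59940) at −2.83 ± 0.10 and ARR9 (AT3G57040) at −2.26 ± 0.12. Auxin response genes fell in 14 of 21 cases and rose in 1 (15 and 1 when adjusted over the list alone), with IAA1 (AT4G14560) at −1.69 ± 0.15. Nitrate response genes fell in 13 of 21 cases and rose in 3, with the nitrate transceptor gene NRT1.1 (AT1G12110) at −2.49 ± 0.18, and hypoxia genes fell in 9 of 14 and rose in 1.

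Phosphate genes, of interest because arsenate enters through phosphate transporters, went both ways: 8 of 27 rose and 11 fell, and the list was not called (adjusted p 0.271). The acid phosphatase gene PAP17 (AT3G17790) rose by 1.70 ± 0.17, and PHF1 (AT3G52190), which brings phosphate transporters out of the endoplasmic reticulum, changed by −1.44 ± 0.11. The transporter gene PHT1;1 (AT5G43350) had a change of −1.59 ± 0.10; it shares most of its sequence with PHT1;2, so 50 bp reads can fall to either copy and its own value is uncertain.

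In total 13003 of 20188 genes changed with arsenic in wild type, 6208 higher and 6795 lower (edgeR, 4 against 4 libraries). The camera test called heat shock (adjusted p 3.14e-80), detoxification (2.11e-26), sulfur (6.25e-14), early stress (2.64e-13), proteasome (1.66e-06) and arsenic transport (0.00527) higher than other genes, and root hair (1.60e-07), endodermis (1.03e-04), cytokinin (5.55e-04), auxin (0.0110), nitrate (0.0252) and hypoxia (0.0413) lower. Over all 135 list tests, heat shock in wild type was the only call that held with an estimated correlation (adjusted p = 0.0484 with an estimated correlation). In the order above, the other lists had adjusted p = 0.0861, 0.122, 0.0861, 0.530, 0.153, 0.504, 0.486, 0.270, 0.530, 0.777 and 0.8292 with an estimated correlation. With an estimated correlation no list call in gl2-5 held either, with an adjusted p of 0.0619 for heat shock.

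The split into higher and lower depended on the scaling. The shares of higher genes among calls were 47.7% in wild type and 46.3% in gl2-5 with TMM, 28.7% and 28.6% with upper-quartile scaling, and 18.18% and 17.404% with library totals alone, as the median of all genes shifted by −0.27 and −0.28 or by −0.52 and −0.58 log2 units. TMM factors were 1.18 to 1.27 in mock and 0.801 to 0.877 in arsenic libraries, and the 10 most abundant genes took 3.01% to 3.51% and 4.27% to 4.86% of counts. The arsenic transport median of 0.38 in wild type and 0.40 in gl2-5 was −0.14 and −0.18 with library totals alone, above medians of all genes of −0.58 and −0.66, with 5 rises and 4 falls in wild type and 6 and 6 in gl2-5. With those totals the proteasome list had 13 rises and 2 falls in wild type (median 0.14), against 26 and 0 with TMM, and 23 rises and 1 fall in gl2-5 (0.37), against 26 and 0. With them the wild-type counts of rises and falls were 16 and 5 for sulfur (19 and 4 with upper-quartile scaling), 32 and 3 for detoxification, 22 and 2 for early stress, 5 and 16 for phosphate and 0 and 10 for epidermal patterning. In gl2-5 they were 18 and 6 for sulfur, 31 and 3 for detoxification, 19 and 3 for early stress, 2 and 31 for root hair, 1 and 11 for endodermis, 1 and 18 for nitrate and 0 and 12 for hypoxia and for epidermal patterning.

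The lists without a call in wild type were mixed. Abscisic acid genes rose in 13 of 23 cases and fell in 4 (adjusted p 0.223), but rose in 6 and fell in 9 with library totals alone. Ribosome biogenesis genes rose in 6 of 17 cases and fell in 1 (0.389), against 1 and 12 with those totals. Jasmonate genes rose in 9 of 24 cases and fell in 4 (0.706), against 3 and 6 with those totals, ethylene genes in 10 and 8 of 22 (0.428; 10 and 9 when adjusted over the list alone), sugar starvation genes in 7 and 1 of 9 (0.193), aquaporins in 5 and 8 of 18 (0.316) and root meristem and cap markers in 2 and 5 of 8 (0.271). Iron deficiency genes rose in 2 of 26 cases and fell in 11 (0.3001), cell cycle genes in 2 and 10 of 23 (0.162; 1 and 9 when adjusted over the list alone) and vascular markers in 1 and 1 of 8 (0.686; 0 when adjusted over the list alone). Unfolded protein response genes rose in 5 of 16 cases and fell in 6 (0.316), and circadian clock genes in 4 and 4 of 12 (0.429); in both lists the median was negative (−0.15 and −0.06) while the mean (0.39 and 0.27) and the test pointed up, as they did in gl2-5. The phosphate list in gl2-5 had a positive median and mean (0.02 and 0.07) and a test that pointed down (adjusted p 0.706); without each library in turn the median was −0.21 to 0.12. With library totals alone ethylene genes rose in 10 cases and fell in 10, sugar starvation genes in 3 and 2, aquaporins in 2 and 13, root meristem and cap markers in 0 and 6, iron deficiency genes in 2 and 18, cell cycle genes in 0 and 22, vascular markers in 0 and 7, unfolded protein response genes in 4 and 10 and circadian clock genes in 3 and 9. Without the 4 libraries with the highest green markers jasmonate genes rose in 3 cases and fell in 1, sugar starvation genes in 4 and 1, and no vascular marker was called. Without wild-type mock 1 or mock 4 the sugar starvation rises were 4. Without wild-type mock 4, arsenic 1 or arsenic 4 the jasmonate falls were 1, and without wild-type mock 2 the iron genes had 4 rises and 7 falls. The 2 cell cycle rises were 0 without wild-type mock 1, 2 or 3 or arsenic 1 or 2, and 1 without wild-type arsenic 4, gl2-5 mock 1 or gl2-5 arsenic 1, 3 or 4. The ribosome biogenesis fall was lost without wild-type mock 1 or 2 or arsenic 1, 3 or 4. The vascular rise was lost without wild-type mock 1 or 3, wild-type arsenic 4, gl2-5 mock 3 or gl2-5 arsenic 3, and the vascular fall without wild-type mock 1 or 4 or arsenic 1. In this list 2 genes fell without wild-type mock 3 or arsenic 4.

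**Figure D2:**
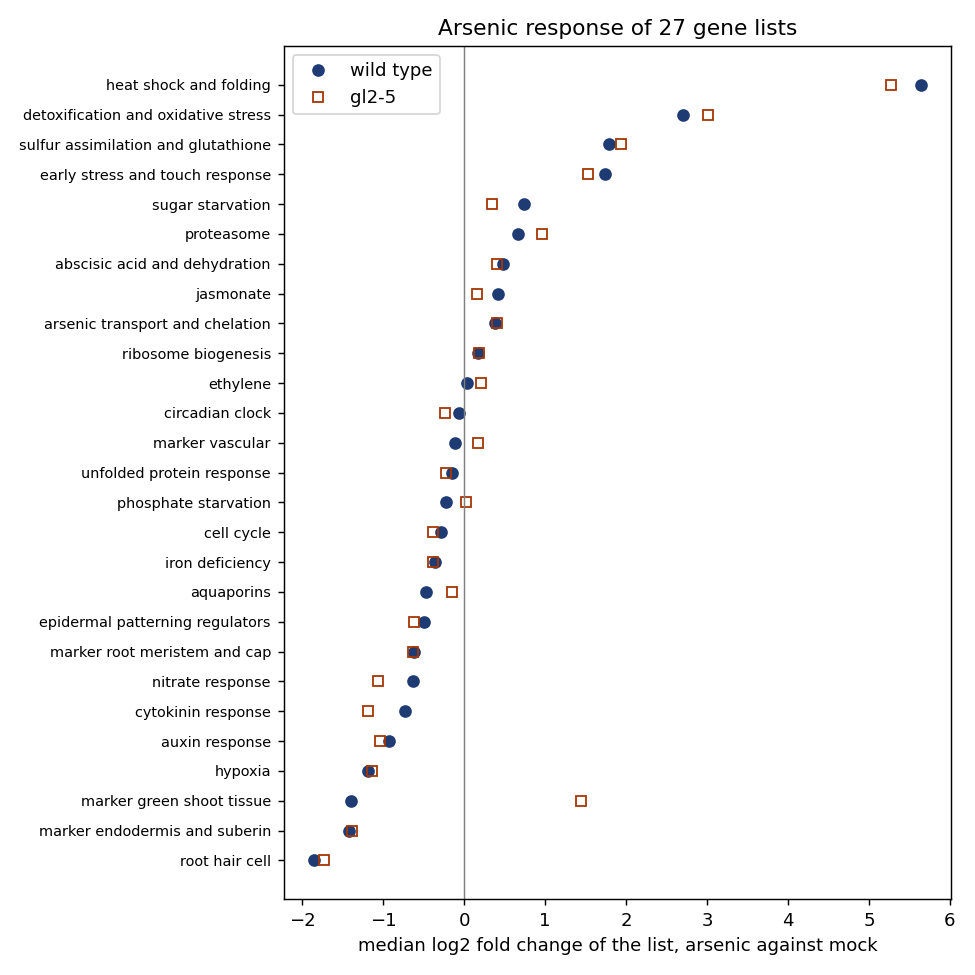
Median log2 fold change of each of 27 gene lists with arsenic against mock, in wild type (filled circles) and gl2-5 (open squares), under TMM scaling. Heat shock has the highest median (5.64 and 5.28) and root hair the lowest (−1.85 and −1.72); with library totals alone the arsenic transport medians are −0.14 and −0.18, above medians of all genes of −0.58 and −0.66.

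Green shoot markers, which should be low in roots, varied between libraries of a group. Their mean was 4.27, 3.41, 1.67 and 5.75 log2 CPM in wild-type mock 1 to 4, 1.69, 3.85, 2.60 and 2.00 in wild-type arsenic 1 to 4, 2.35, 1.91 and 3.23 in gl2-5 mock 1 to 3, and 2.72, 5.56, 2.27 and 2.25 in gl2-5 arsenic 1 to 4. The 4 highest were wild-type mock 1 and 4, wild-type arsenic 2 and gl2-5 arsenic 2. On the second principal component of all genes, with 5.6% of the variance, these 4 lay at 27.4 to 40.4. Every other library lay at or below −0.34. Within wild-type mock, Pearson r was 0.986 for 1 with 4 and 0.990 for 2 with 3, against 0.976 to 0.980 between these pairs. In wild type 6 of the 15 markers fell with arsenic and 1 rose (median −1.39; 2 fell when adjusted over the list alone; camera adjusted p 0.389), and 0 fell without wild-type mock 4, 2 without arsenic 1, 10 without arsenic 2 and 3 without arsenic 4. The median was −0.52 without wild-type mock 4. Without the 2 libraries with the highest markers 1 fell, and without the 4 with the highest 0. The rise was lost without wild-type mock 1, 2 or 3 or arsenic 1, 2 or 4. In gl2-5 1 marker rose and 0 fell (median 1.45, adjusted p 0.683), with a median of −0.08 without gl2-5 arsenic 2. The count of rises was 2 without wild-type mock 3 or gl2-5 arsenic 1, and 5 without wild-type mock 4, while 2 rose and 2 fell without the 4 libraries.

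With arsenic in gl2-5 all 30 heat shock genes rose (median 5.28), with ATHSP22.0 up by 8.36 ± 0.43, HSFA2 by 5.06 ± 0.12 and HSP70 by 4.49 ± 0.11 (SE, n = 4 and 3 libraries). BGLU28 rose by 10.14 ± 0.47, CRK39 by 8.77 ± 0.43, the related glucosidase gene BGLU27 (AT3G60120) by 8.39 ± 0.44 and APX2 by 7.71 ± 0.28. SHM7, APS3 and GSTU10 rose by 4.43 ± 0.16, 4.55 ± 0.17 and 4.54 ± 0.16, and the transporter genes ABCC2 and ABCC3 (AT3G13080) by 2.87 ± 0.10 and 2.81 ± 0.17. ATS9, CDC48 and PAP17 rose by 2.51 ± 0.11, 2.00 ± 0.11 and 2.35 ± 0.20.

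Falls in gl2-5 took in CYP718 at −5.68 ± 0.28, RAP2.11 (AT5G19790), an ethylene-class transcription factor of potassium response, at −5.50 ± 0.42, XTH13 at −5.07 ± 0.31, FLA6 at −5.04 ± 0.38 and PRP1 at −4.84 ± 0.34. The hair genes RHD6 (AT1G66470), RSL4 and SHV2 changed by −3.30 ± 0.20, −2.97 ± 0.18 and −3.85 ± 0.24, although the mutant lacks most GL2 transcript. The remaining GL2 transcript changed by −1.76 ± 0.32 and ATMYC1 by −2.20 ± 0.23. CASP4 and PER64 changed by −4.07 ± 0.31 and −2.48 ± 0.14, ARR3 by −2.04 ± 0.11, the nitrate-responsive repressor LBD38 (AT3G49940) by −1.40 ± 0.07, and PHT1;1, with the same doubt about its copies, by −1.45 ± 0.11.

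In gl2-5 13028 genes changed, 6028 higher and 7000 lower (edgeR, 4 against 3 libraries). Detoxification genes rose in 33 of 37 cases (34 when adjusted over the list alone; median 3.01), sulfur genes in 21 of 26 with 1 fall, early stress genes in 22 of 29 with 1 fall, proteasome genes in 26 of 27 (27 when adjusted over the list alone; median 0.96) and arsenic transport genes in 7 of 13 with 1 fall. Root hair genes fell in 30 of 38 cases with 7 rises (median −1.72), endodermis genes in 10 of 13 with 2 rises (3 when adjusted over the list alone), cytokinin genes in 6 of 10, auxin genes in 15 of 21, and nitrate genes in 14 of 21 with 3 rises. Hypoxia genes fell in 9 of 14 cases, and the list missed the threshold (adjusted p 0.0769; interaction 0.501). It was called without the 2 or the 4 libraries with the highest green markers (0.0362 and 0.0397). The sulfur fall was lost without gl2-5 mock 2 or arsenic 1 or 4 and the early stress fall without gl2-5 mock 2 or 3 or arsenic 1, 2 or 4. Arsenic transport had 2 falls without gl2-5 arsenic 3 and the endodermis list 1 rise without gl2-5 mock 1 or 3. Camera adjusted p values were 1.57e-64 for heat shock, 7.71e-26 for detoxification, 2.32e-15 for sulfur, 6.27e-11 for early stress, 8.47e-12 for proteasome, 0.00200 for arsenic transport, 3.66e-08 for root hair, 7.18e-04 for endodermis, 0.00224 for cytokinin, 0.0116 for auxin and 0.00639 for nitrate.

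Arsenic calls were shared between genotypes. Of the wild-type calls 11074, or 85.2%, were also called in the same direction in gl2-5. Higher in both were 5337 genes, against 1854 if the calls were independent, and lower in both were 5737, against 2356. Called in opposite directions were 2 genes higher in wild type and lower in gl2-5, and 8 genes the other way. Log2 changes correlated at r of 0.91 across all genes, which are not independent replicates.

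**Figure D3:**
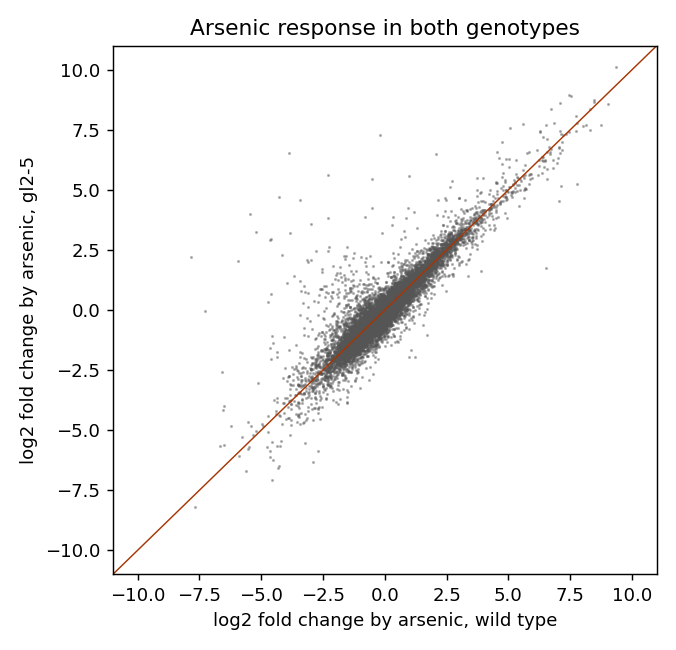
Log2 fold change with arsenic in wild type (horizontal) and in gl2-5 (vertical), 1 point per tested gene (20188 genes), with the line of equal change. The points follow the line with r of 0.91 across genes.

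Between genotypes in mock, gl2-5 had lower transcripts of ATCSLB05, XTH17 and PIP2;4, and higher transcripts of HAK5, PLA2A and the root hair regulators RSL2 and LRL3. The cellulose synthase-like gene ATCSLB05 (AT4G15290) was lower in gl2-5 with a log2 difference of −3.59 ± 0.24, and the xyloglucan-modifying gene XTH17 (AT1G65310) with −3.03 ± 0.24. The aquaporin gene PIP2;4 (AT5G60660) had −1.58 ± 0.22, the galactinol synthase gene GolS3 (AT1G09350) −1.39 ± 0.12 and the arabinogalactan gene AGP30 (AT2G33790) −1.22 ± 0.22 (SE, n = 3 gl2-5 and 4 wild-type libraries). The potassium transporter gene HAK5 (AT4G13420) was higher by 2.196 ± 0.21, from 5.05 ± 0.884 to 23.3 ± 5.95 CPM (SD, adjusted p 2.68e-05). PLA2A (AT2G26560), a patatin-like lipase gene, was higher by 2.03 ± 0.25, the kinase gene CIPK17 (AT1G48260) by 1.67 ± 0.22, and the hair regulators RSL2 (AT4G33880) and LRL3 (AT5G58010) by 1.54 ± 0.18 and 0.92 ± 0.12.

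Other named genes also differed in mock. The calcium sensor gene CML37 (AT5G42380) was higher by 1.17 ± 0.14, and the heat shock factor genes HSFA3 (AT5G03720) and HSFA7A (AT3G51910) by 0.95 ± 0.18 and 0.80 ± 0.15; both factors lost their call without the 4 libraries with the highest green markers (adjusted p 0.144 and 0.0718). The phosphate transporter gene PHT1;4 (AT2G38940) had −0.99 ± 0.16, NLM1 (AT4G19030), an aquaglyceroporin gene of the arsenic transport list, −0.92 ± 0.16, and ARR3 −0.74 ± 0.10. The peptide transporter gene PTR5 (AT5G01180) was higher by 1.69 ± 0.37 (adjusted p 0.0236), a call that ended without wild-type mock 1, 2 or 4 or gl2-5 mock 1 or 3 (0.0525 to 0.101). It ended also with limma-voom (0.193), thinning to the smallest library (0.0525), the green markers as a covariate (0.0544) and without the 4 libraries with the highest of these markers (0.13). The vacuolar water channel genes DELTA-TIP (AT3G16240), TIP2 (AT3G26520) and TIP2;2 (AT4G17340) had −0.98 ± 0.21, −0.60 ± 0.14 and −0.49 ± 0.11. Their calls ended without wild-type mock 4, gl2-5 mock 1 or gl2-5 mock 2, those of TIP2 and TIP2;2 also without wild-type mock 2, with adjusted p between 0.0604 and 0.138, and all 3 ended without the 2 libraries with the highest green markers (0.0610, 0.0840 and 0.0729). Those of DELTA-TIP and TIP2;2 ended without the 4 highest (0.104 and 0.15), and those of TIP2 and TIP2;2 with the markers as a covariate (0.0754 and 0.0643).

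In total 571 genes differed in mock, 342 higher and 229 lower in gl2-5, and DESeq2 called 1066. Single libraries moved the count: it was 272 without wild-type mock 1, 230 without wild-type mock 4, 236 without gl2-5 mock 1 and 279 without gl2-5 mock 2. It was 254 without the 2 libraries with the highest green markers, 93 without the 4 with the highest, 273 with these markers as a covariate, 368 when only these groups were fitted, and 24 in the test against a 1.5-fold change. The excess of higher over lower genes did not hold in each of these fits. It turned without wild-type mock 4 (113 higher and 117 lower), without the 4 libraries (34 and 59) and in the test against a 1.5-fold change (10 and 14), and was 128 against 126 without the 2 libraries and 141 against 131 without wild-type mock 1.

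Among the lists in mock, camera called root hair higher in gl2-5 (median 0.43, adjusted p 3.70e-13; adjusted p = 0.397 with an estimated correlation), with 7 of 38 genes higher (16 when adjusted over the list alone). That count was 2 without gl2-5 mock 1, 11 without gl2-5 mock 2, 4 without wild-type mock 2, gl2-5 arsenic 1, arsenic 3 or arsenic 4, and 3 without any of wild-type mock 1, 3 or 4, wild-type arsenic 1, 2 or 3, or gl2-5 mock 3. It was 11 with DESeq2, 4 with thinning, 2 without the 4 libraries with the highest green markers and 3 without the 2 highest, with these markers as a covariate, with upper-quartile scaling, with the replicate block in all groups or with only these groups fitted. The median was 0.27 without gl2-5 mock 1. Heat shock genes were higher (median 0.46, 2.50e-16; adjusted p = 0.397 with an estimated correlation), 6 of 30 over all genes and 16 when adjusted over the list alone. The 6 became 11 with DESeq2, 10 with library totals alone, and 3 with only these groups fitted, without the 2 libraries with the highest green markers or with the markers as a covariate. Without wild-type mock 4 the 6 became 3, without gl2-5 mock 3 they became 2, and without the 4 libraries with the highest green markers 0, with a median of 0.19 and the list still called (3.28e-06). Aquaporins were lower (median −0.22, 2.69e-08; adjusted p = 0.115 with an estimated correlation), 4 of 18 over all genes and 5 when adjusted over the list alone, with 2 without wild-type mock 2 and 1 without wild-type mock 4, gl2-5 mock 1 or gl2-5 mock 2. The count was 1 without the 2 libraries with the highest green markers and 2 with the markers as a covariate. Sugar starvation genes were higher (median 0.70, 8.91e-09; adjusted p = 0.153 with an estimated correlation) with 0 of 9 called over all genes by edgeR, 5 by DESeq2 and 9 when adjusted over the list alone. The median was 0.36 without the 4 libraries with the highest green markers. Of these, wild-type mock 1 and 4 had list means of 4.96 and 5.35 log2 CPM, against 5.80 and 5.85 in wild-type mock 2 and 3. The edgeR count was 4 without wild-type mock 3, 2 without wild-type arsenic 4, 1 without wild-type mock 2 or gl2-5 arsenic 2 or 4, and 0 without each other library. It was 2 with library totals alone or with either replicate block, and 1 with only these groups fitted.

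Smaller list differences in mock were vascular markers (median −0.43, adjusted p 2.13e-04; adjusted p = 0.266 with an estimated correlation), early stress (0.26, 0.00164; adjusted p = 0.492 with an estimated correlation), cytokinin (−0.24, 0.0150; adjusted p = 0.486 with an estimated correlation), phosphate (−0.14, 0.0209; adjusted p = 0.558 with an estimated correlation) and unfolded protein response (0.11, 0.0477; adjusted p = 0.637 with an estimated correlation). The detoxification list was higher (0.12, 0.0230; adjusted p = 0.821 with an estimated correlation) and turned lower, without a call, when the 4 libraries with the highest green markers were left out (adjusted p 0.404). The green shoot markers themselves were lower (−1.66, 0.00224; adjusted p = 0.7499 with an estimated correlation). Without these 4 libraries the early stress call ended (0.262, median 0.05), as did that of the green markers (0.964, median −0.05). The unfolded protein response call ended with RLE scaling (0.0506) and without the 2 libraries with the highest green markers (0.0571), which also ended the detoxification call (0.25). Single libraries moved medians too. Early stress had 0.11 without gl2-5 mock 3. The unfolded protein response had −0.04 without gl2-5 mock 1 and 0.17 without gl2-5 mock 3. Phosphate had −0.08 without gl2-5 mock 2 and −0.29 without gl2-5 mock 3. Detoxification had −0.03, 0.04 and 0.02 without wild-type mock 1, wild-type mock 4 or gl2-5 mock 3, and green markers −0.73 without wild-type mock 4. The epidermal patterning list was called lower (0.0252; adjusted p = 0.514 with an estimated correlation) with a positive median of 0.05 (−0.07 to 0.10 without each library in turn, negative without gl2-5 mock 3) and a negative mean of −0.23, and GL2 was its only called gene over all genes tested. As GL2 is the mutated gene and the list was not tested without it, the epidermal patterning call does not speak for the other members. The arsenic transport list was not called (adjusted p 0.756), with a median of 0.03 (−0.05 to 0.08 without each library in turn) and a mean of −0.05. Iron deficiency (median −0.05, 0.341), jasmonate (−0.08, 0.241) and proteasome (−0.08, 0.0552) had no call, and all 3 were called lower without the 4 libraries with the highest green markers (0.00144, 0.00957 and 0.0174). Without each library in turn their medians were −0.17 to 0.07, −0.21 to 0.01 and −0.11 to −0.01.

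**Figure D4:**
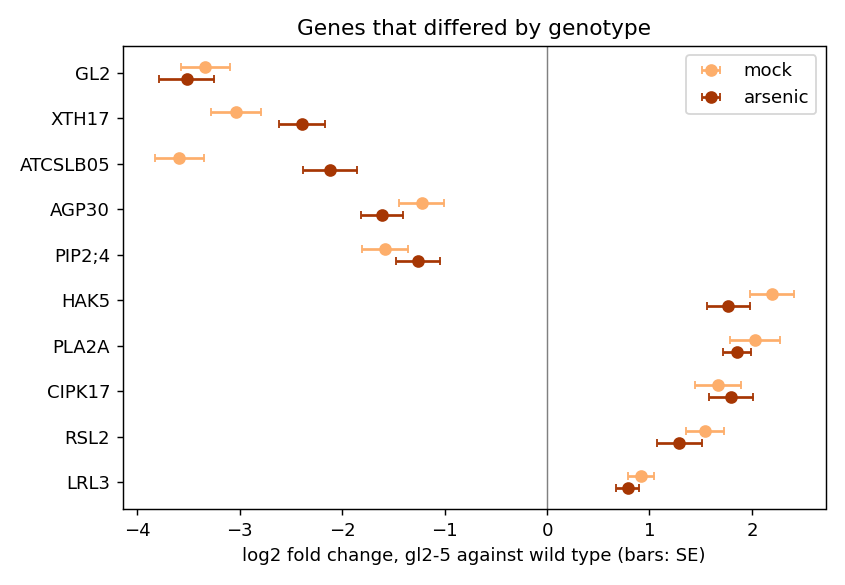
Log2 fold change of gl2-5 against wild type in mock and in arsenic for 10 named genes, with bars of 1 SE. GL2, XTH17, ATCSLB05, AGP30 and PIP2;4 are lower and HAK5, PLA2A, CIPK17, RSL2 and LRL3 higher in both conditions.

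Between genotypes in arsenic, gl2-5 had lower transcripts of XTH17, ATCSLB05, AGP30 and PIP2;4, and higher transcripts of PLA2A, CIPK17, HAK5, RSL2 and LRL3, genes that also differed in mock. RWP1, a suberin gene, and the camalexin pathway gene CYP71A12 were among others with higher transcripts. XTH17 was lower with −2.39 ± 0.22, ATCSLB05 with −2.12 ± 0.27, AGP30 with −1.61 ± 0.20 and PIP2;4 with −1.26 ± 0.21 (SE, n = 4 and 4 libraries). PLA2A, CIPK17, HAK5, RSL2 and LRL3 were higher by 1.85 ± 0.14, 1.80 ± 0.21, 1.77 ± 0.21, 1.29 ± 0.22 and 0.79 ± 0.11, and the kinase gene PERK13 (AT1G70460) of hair cells by 0.93 ± 0.14. ABCG16 (AT3G55090), an ABC transporter gene, was higher by 1.67 ± 0.16. RWP1 (AT5G41040), which adds ferulate to suberin, was higher by 1.48 ± 0.15, from 42.5 ± 8.74 to 119 ± 15.2 CPM (SD, adjusted p 5.38e-05). The suberin acyltransferase gene GPAT5 (AT3G11430) was higher by 0.83 ± 0.16 and the reductase gene FAR4 (AT3G44540) by 0.51 ± 0.12. Without the 4 libraries with the highest green markers the calls of GPAT5 and FAR4 ended (adjusted p 0.0556 and 0.101), and that of FAR4 ended also without wild-type arsenic 1, arsenic 2 or gl2-5 arsenic 4 (0.0626 to 0.0663).

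CYP71A12 was higher by 1.40 ± 0.17, the alternative oxidase gene AOX1D (AT1G32350) by 1.54 ± 0.23 and ABCC3 by 0.80 ± 0.14. The threonine aldolase gene THA1 (AT1G08630) was higher by 1.98 ± 0.45, but lost its call without wild-type arsenic 3 or gl2-5 arsenic 4 (adjusted p 0.0522 to 0.0565). PP2-A5 (AT1G65390), a phloem lectin-like gene, had −1.83 ± 0.38, with no call without the 4 libraries with the highest green markers (0.0539). The iron regulator FRU (AT2G28160) had −1.15 ± 0.18, and the nitrate-responsive repressors LBD39 (AT4G37540) and LBD38 had −0.66 ± 0.11 and −0.51 ± 0.07. The patterning genes CPC (AT2G46410) and TRY (AT5G53200), small MYB proteins that promote hair fate, had −0.50 ± 0.11 and −1.31 ± 0.34. The CPC call ended without wild-type arsenic 2 or 3 (0.0526 to 0.0608), with thinning to the smallest library (0.0717) and without the 4 libraries with the highest green markers (0.0507). The TRY call ended without wild-type arsenic 1, 2 or 3 or gl2-5 arsenic 1, 2 or 4 (0.0613 to 0.120), with thinning (0.1) and without the 2 or the 4 libraries (0.0781 and 0.196). TRY was at 0.679 ± 0.180 CPM in wild type and 0.263 ± 0.0715 in gl2-5, so its change rests on few reads.

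In total 1014 genes differed in arsenic, 595 higher and 419 lower in gl2-5 (58.7% higher), with 48.4% higher under upper-quartile scaling and 39.1% with library totals alone. DESeq2 called 1521. The count was 570 without wild-type arsenic 1, 514 without wild-type arsenic 2, 558 without wild-type arsenic 3, 555 without gl2-5 arsenic 1, 566 without gl2-5 arsenic 4, 504 without the 4 libraries with the highest green markers and 34 in the test against a 1.5-fold change. Of the genes called in mock, 106 were higher in gl2-5 in both conditions, against 10.08 if the calls were independent, and 76 lower in both, against 4.75. Across all genes the genotype differences in mock and in arsenic correlated at r of 0.221.

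Among the lists in arsenic, proteasome was higher in gl2-5 (median 0.24, camera adjusted p 2.97e-12; adjusted p = 0.406 with an estimated correlation), with 8 of 27 genes called over all genes and 18 when adjusted over the list alone. RPT2a (AT4G29040), an ATPase subunit gene, was higher by 0.39 ± 0.08 and CDC48 by 0.43 ± 0.10, the latter without a call when wild-type arsenic 2 or 3 or gl2-5 arsenic 1 was left out (adjusted p 0.0608 to 0.0654). The 8 became 5 without wild-type mock 3, 4 without wild-type arsenic 1, 2 without gl2-5 arsenic 4, and 1 without wild-type arsenic 2, wild-type arsenic 3 or gl2-5 arsenic 1. They became 14 with DESeq2, 2 without the 4 libraries with the highest green markers, and 4 with library totals alone, without the count filter or with only these groups fitted. Root hair was higher (median 0.38, 1.62e-08; adjusted p = 0.487 with an estimated correlation), with 7 of 38 called (11 higher and 1 lower when adjusted over the list alone), 4 without wild-type arsenic 2, 3 without gl2-5 arsenic 1 and 11 with DESeq2. Detoxification was higher (median 0.22, 2.26e-07; adjusted p = 0.486 with an estimated correlation), with 4 of 37 called (7 when adjusted over the list alone), 7 with DESeq2 or with only these groups fitted, and 9 with the green markers as a covariate.

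Other lists called in arsenic were sulfur (median 0.23, 2.32e-04; adjusted p = 0.492 with an estimated correlation), aquaporins (−0.19, 0.00199; adjusted p = 0.462 with an estimated correlation), jasmonate (−0.47, 0.00495; adjusted p = 0.7499 with an estimated correlation), heat shock (0.19, 0.00551; adjusted p = 0.8292 with an estimated correlation), cell cycle (−0.16, 0.00595; adjusted p = 0.682 with an estimated correlation) and epidermal patterning (−0.11, 0.0123; adjusted p = 0.492 with an estimated correlation). Early stress (0.15, 0.0284; adjusted p = 0.673 with an estimated correlation), sugar starvation (0.17, 0.0292; adjusted p = 0.673 with an estimated correlation) and green shoot markers (0.91, 0.0435; adjusted p = 0.8292 with an estimated correlation) were higher. Without the 4 libraries with the highest green markers the jasmonate and cell cycle calls ended (0.226 and 0.115), and without the 2 with the highest the epidermal patterning and cell cycle calls ended (0.0527 and 0.0911). The green marker call ended in both fits (0.131 and 0.906), with RLE scaling (0.0784) and with the replicate number as a block in the arsenic groups (0.0528). Its median was −0.13 without gl2-5 arsenic 2. The median of jasmonate was −0.20 without wild-type arsenic 2 or 3. That of cell cycle was −0.08, −0.25, −0.11 and −0.10 without wild-type arsenic 3, wild-type arsenic 4, gl2-5 arsenic 2 and gl2-5 arsenic 4. That of aquaporins was −0.10 and that of sugar starvation 0.30 without wild-type arsenic 4. With library totals alone the medians of sugar starvation and early stress were 0.11 and 0.08. With the green markers as a covariate that of early stress was 0.22. That of epidermal patterning was −0.07 without wild-type arsenic 1 or gl2-5 arsenic 2, −0.05 without wild-type arsenic 3 and −0.19 without wild-type arsenic 4. It was −0.18 without gl2-5 arsenic 1, −0.17 without gl2-5 arsenic 3 and −7.10e-04 without gl2-5 arsenic 4. The epidermal patterning list holds GL2, the mutated gene, at −3.52 ± 0.27 (SE) in arsenic. It was not tested without GL2, so its call does not speak for the other members.

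The libraries of the 2 arsenic groups were taken as paired by replicate number, and 2 lists without a call moved with the number as a block. Endodermis and suberin markers had 3 genes higher of 13, RWP1, GPAT5 and FAR4 (4 higher and 2 lower when adjusted over the list alone; median 0.10, adjusted p 0.0799; adjusted p = 0.821 with an estimated correlation). The list stayed without a call with the block in the arsenic groups (0.0606) and was called higher with the block in all groups (0.0126). Its median was 0.04, 0.16, 0.01 and 0.03 without wild-type arsenic 1, 3, 4 and gl2-5 arsenic 3, and without the 4 libraries with the highest green markers 1 gene was higher (median 0.17). Abscisic acid genes, 1 higher and 1 lower of 23 (5 and 2 when adjusted over the list alone; median 0.10, adjusted p 0.0516; adjusted p = 0.627 with an estimated correlation), were called higher with the block in the arsenic groups (0.0493) or in all groups (0.0357), and without the 4 libraries with the highest green markers (0.00988). Their rise was lost without wild-type arsenic 1 or 3 or gl2-5 arsenic 3 or 4, became 2 without wild-type arsenic 2 or gl2-5 mock 1 or 3, and the fall was lost without gl2-5 arsenic 1. The median was 0.18 without wild-type arsenic 2 or 3 or without the 4 libraries. With library totals alone 0 were higher and 2 lower, with DESeq2 4 and 1, without the 4 libraries 2 and 1, and the rise was lost with limma-voom, thinning and the block in all groups.

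The interaction, which asks whether gl2-5 responded to arsenic differently from wild type, had 0 called genes in edgeR, with 2269 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0781. limma-voom called 0 and DESeq2 169. The edgeR count was 3 without gl2-5 mock 3, 2 without wild-type mock 3, 1 without wild-type arsenic 2 and 1 without wild-type arsenic 4. With the replicate number as a block in the arsenic groups, whose libraries were taken as paired, edgeR called 20 genes, 17 of them with a more positive response in gl2-5, and with the block in all groups 2. The 5 genes with the smallest p, given as values without a call, were the ferric reductase-like gene AT3G07570 at 0.71 ± 0.11, the Rossmann-fold gene AT2G23910 at 1.26 ± 0.20, the nucleotide transporter gene NTT1 (AT1G80300) at 0.75 ± 0.13, the major facilitator gene AT5G25050 at 1.199 ± 0.20 and the MYB gene MYB50 (AT1G57560) at 0.97 ± 0.17 (log2, SE). HSFA7A had −1.11 ± 0.21 and ARR3 0.79 ± 0.15. All 7 had an edgeR adjusted p of 0.0781. DESeq2 called each of them (adjusted p 1.2e-05 to 0.00298), and edgeR with the block in the arsenic groups called the first 5 (0.0127 to 0.0375).

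Of the lists, proteasome rose more with arsenic in gl2-5 (median interaction 0.33, camera adjusted p 6.89e-17; adjusted p = 0.266 with an estimated correlation), with 0 genes called over all genes, 3 by DESeq2 and 18 of 27 when adjusted over the list alone. The mean of its members was 6.90 ± 0.0339 log2 CPM in wild-type mock (SD, n = 4), 7.65 ± 0.0570 in wild-type arsenic (n = 4), 6.83 ± 0.0820 in gl2-5 mock (n = 3) and 7.89 ± 0.137 in gl2-5 arsenic (n = 4). Without each library in turn the median interaction stayed at 0.25 to 0.37. Heat shock rose less in gl2-5 (−0.27, 1.65e-06; adjusted p = 0.626 with an estimated correlation). That call ended without the 4 libraries with the highest green markers (0.262). The median was −0.17, −0.46, −0.18 and −0.13 without wild-type mock 1, 2, 4 and gl2-5 mock 3. Arsenic transport (0.22, 0.0552), jasmonate (−0.37, 0.223) and nitrate (−0.17, 0.0663) were not called, but were with the block in the arsenic groups (0.0432, 0.0432 and 0.0495). Arsenic transport was called also without the 2 or the 4 libraries with the highest green markers (0.0111 and 0.00938), and ethylene (0.10, 0.160) without the 4 (0.0113). Arsenic transport, jasmonate and nitrate had adjusted p = 0.437, 0.857 and 0.824 with an estimated correlation. Single libraries moved these medians: without each in turn they were 0.12 to 0.25, −0.50 to −0.16 and −0.27 to 0.07, and that of ethylene −0.01 to 0.19. The nitrate median was positive only without wild-type arsenic 3, and that of jasmonate was −0.01 without the 4 libraries. For root hair genes no difference in the arsenic response was detected (−0.07, 0.458), with medians of −0.24 to 0.14 without each library in turn.

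**Figure D5:**
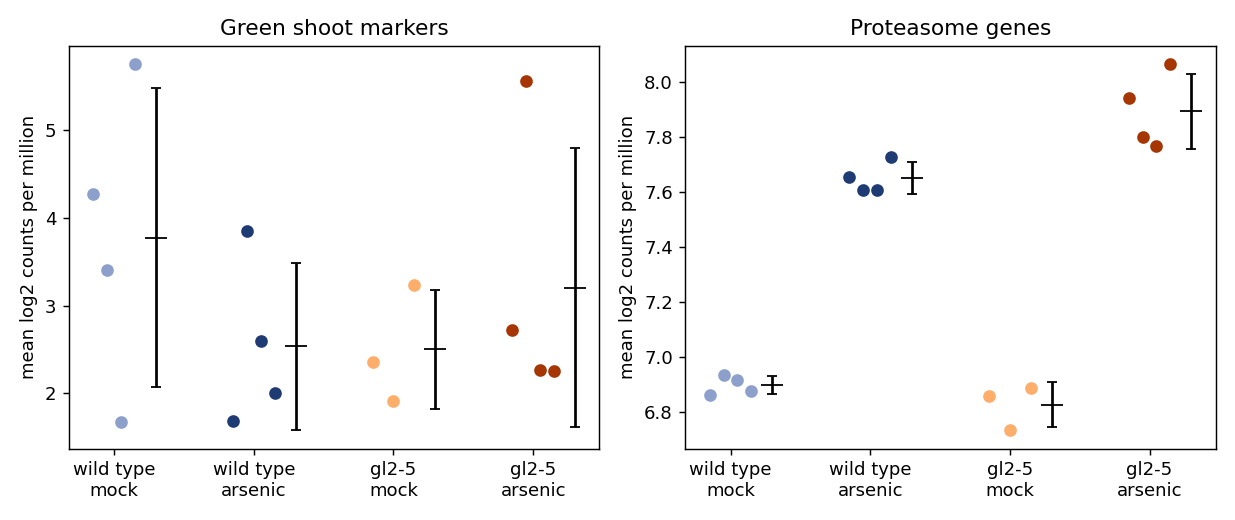
Mean log2 CPM of the green shoot markers (left) and of the proteasome genes (right) for each library (points), with the mean and SD of each group (bars). Green markers reach 5.75 in wild-type mock 4 and 5.56 in gl2-5 arsenic 2, and proteasome genes are highest in gl2-5 arsenic, at 7.77 to 8.06.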

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

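Chosen only after the result was seen were the test of arsenic or genotype as the source of the green marker levels, the test of the 2 wild-type mock libraries with shoot markers, the test of a common share of carried reads, the scaling by library totals, the fit with green markers as a covariate, the fit with a block in the arsenic groups, and the choice to fit without the libraries highest in these markers. The bounds of the proteasome test without 4 of these libraries were written before its value was computed, and the other tests were set before their result was computed. Libraries far from the rest of their group were sought in 342 groups of 4 libraries, for the levels of the lists and of the named genes. Chance marks about 1 in 20 such groups, or 17 here, and 9 were marked, so single cases carry little weight.

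In gl2-5 arsenic 2 the detoxification list lay at 8.11 log2 CPM (others 8.34 to 8.35), the green shoot markers at 5.56 (others 2.25 to 2.72) and AOX1D at 4.36 (others 5.56 to 5.63). In gl2-5 arsenic 1 ABCG16 lay at 5.15 (others 5.5 to 5.57) and PERK13 at 4.22 (others 3.94 to 3.96). PERK13 lay at 3.55 in wild-type mock 1 (others 4.06 to 4.14), where PHF1 lay at 5.61 (others 5.24 to 5.25). ARR9 lay at 3.71 in wild-type arsenic 1 (others 4.08 to 4.16) and SCR at 3.67 in wild-type arsenic 4 (others 4.06 to 4.10).

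The arsenic response of 9 lists differed between genotypes in the camera test of the interaction. In gl2-5 the response was more positive for proteasome (adjusted p 6.89e-17), green shoot markers (4.14e-07), sulfur assimilation and glutathione (1.24e-04), phosphate starvation (0.00304), vascular markers (0.00969) and aquaporins (0.0435). It was more negative for heat shock (1.65e-06), sugar starvation (0.00304) and the unfolded protein response (0.0413). With an estimated correlation none of these was called, at adjusted p of 0.266, 0.504, 0.486, 0.486, 0.486, 0.623, 0.626, 0.504 and 0.627 in that order. The calls of sugar starvation, heat shock and green markers ended without the 4 libraries highest in green markers (0.287, 0.262 and 0.155), and that of aquaporins without the 2 highest (0.076). That of the unfolded protein response ended with RLE scaling (0.0527) and with the replicate block in the arsenic groups (0.0583). Medians also moved by over 1.5 times without single libraries, in the same direction. They moved without wild-type arsenic 4 for sugar starvation (−0.54 to −0.33), without wild-type mock 4 or gl2-5 arsenic 2 for green markers (2.58 to 1.64 or 1.01), without gl2-5 arsenic 1 for vascular markers (0.36 to 0.23). They moved also without wild-type mock 1, gl2-5 mock 3 or gl2-5 arsenic 2 for phosphate (0.25 to 0.14, 0.45 or 0.16), without gl2-5 mock 1, gl2-5 mock 3 or wild-type arsenic 3 for the unfolded protein response (−0.12 to −0.03, −0.22 or −0.07). For aquaporins the median moved without wild-type mock 1, wild-type arsenic 4, gl2-5 mock 1, gl2-5 mock 3 or gl2-5 arsenic 2 (0.09 to 0.14, 0.14, 0.02, 0.17 or 0.13). Called over all genes in the interaction by edgeR were 0 genes, with 2269 at an unadjusted p under 0.05, 169 called by DESeq2 and 20 by edgeR with the block in the arsenic groups.

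The green shoot markers ranged over as much as 4.08 log2 units within wild-type mock. Arsenic or genotype as the whole source of this spread is argued against, because libraries of a group share both, yet wild-type mock lay at 1.67 to 5.75 and gl2-5 arsenic at 2.25 to 5.56. The largest range within a group was 3.20 times the largest difference between group means. A part of arsenic or genotype in the differences between groups stays open. Shoot tissue carried into some root samples stays open. It predicts that shoot genes outside photosynthesis rise in the same libraries, and for the 5 of these that passed the count filter Pearson r of the deviations within groups was 0.474 (permutation p 0.236, Spearman rho 0.375 with permutation p 0.268, 15 libraries), or 0.377 without gl2-5 arsenic 2 and wild-type mock 4, which lies between the bounds set for and against it. Whether shoot tissue was carried in stays undecided for these libraries, because r of the mean of only 5 genes lay between the bounds. The 5 genes were not alike. In all 5 contrasts CER1, ATML1 and TCP4 had the sign of the green marker median, while PDF1 and KCS10 had it in some only. Of their changes, that of TCP4 with arsenic in gl2-5 alone had a call (edgeR adjusted p 0.0139). These contrasts share groups and do not compare libraries within a group, so they do not decide it. Greening of the roots themselves was not tested.

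Heat shock genes were higher in gl2-5 mock than in wild-type mock, with a median of 0.46. Reads carried over from arsenic libraries may account for a part of it. The median excess of 198 other strongly induced genes, relative to the gl2-5 arsenic level, was 1.18 times that of 26 list genes (bootstrap 95% interval 0.626 to 1.96). The bound set for a common share left carried reads open as the whole source. A common share would put the same excess in every member, but the median was 1.11% in the 15 less induced and 0.333% in the 15 more induced members, a ratio of 3.34 (bootstrap 95% interval 1.93 to 8.60), with 17.0% for HSFA3 and 11.6% for HSFA7A, while the whole gl2-5 mock level of BGLU28 was 0.0877% of its arsenic level. The bound set first was an interval above 2, which this ratio misses; a bound of 1, tried after the interval had been seen, would argue against a common share as the whole source. The libraries with shoot markers may account for it too: without wild-type mock 1 and 4 the median fell to 0.19. A difference of genotype stays open: without the 4 libraries highest in green markers the list was still called higher in gl2-5 (adjusted p 3.28e-06, median 0.19), with 0 of its genes called.

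Proteasome genes rose more with arsenic in gl2-5 than in wild type, with a median interaction of 0.33. A trend with expression level or gene length is argued against, as the median lay at percentile 100 of 10000 random lists matched for both, whose upper bound was 0.10. The libraries with shoot markers are argued against as well, since without the 4 highest the median was 0.37, although the genes called higher in gl2-5 under arsenic fell from 8 to 2. A stronger proteasome response in gl2-5 is therefore a hypothesis that these tests leave standing, limited by the adjusted p of 0.266 with an estimated correlation and by 0 genes called over all genes. Members of the list are co-regulated, so the number of independent observations is the 15 libraries and not the 27 genes.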

How the results depend on the processing

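The scaling by library totals, the fits without the 2 or the 4 libraries highest in green markers, the fit with these markers as a covariate and the replicate block in the arsenic groups were chosen after the data had been seen. Counts of called genes stayed within 1.5 times those reported for arsenic in both genotypes under every alternative except the test against a 1.5-fold change, which by its construction left 5727 in wild type and 6148 in gl2-5. These totals hide changes of direction and of genes. With library totals alone 2979 were higher and 13409 lower in wild type, against 6208 and 6795 with TMM. In gl2-5 they were 2846 and 13507, against 6028 and 7000. Of the TMM calls, 10661 and 10773 were also called with those totals, in either direction. Leaving out each library in turn gave 12125 to 13101 and 12025 to 13102. The overlap of arsenic calls between genotypes kept its size with the stricter filter, the replicate block and DESeq2, and was not computed under the other alternatives. The 571 genes that differed in mock became 1066 with DESeq2, 24 against a 1.5-fold change, 368 with only the groups compared, 254 without the 2 libraries highest in green markers, 93 without the 4 highest and 273 with these markers as a covariate, and 230 to 676 without each library in turn. DESeq2 shared 567 of its calls with them. The 1014 in arsenic became 1521 with DESeq2, 34 against a 1.5-fold change, 504 without the 4 libraries and 514 to 1401 without each library in turn. The cause was not tested; without wild-type arsenic 4 both counts rose, to 676 and 1401. The interaction count of 0 became 169 with DESeq2, 20 with the replicate block in the arsenic groups, 2 with the block in all groups and 0 to 3 without each library in turn. The cause was not tested. In simulated data DESeq2 made more false calls than edgeR for the interaction (26 against 8). It also recovered more of the changed genes there (43.3% against 28.4% at 1.5-fold, 79.1% against 68.7% at 2-fold).

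Of 135 list tests 56 were called, against 53 with RLE scaling, 62 with the replicate block, 59 with the block in the arsenic groups, 53 and 55 without the 2 and the 4 libraries, and 1 with an estimated correlation. These totals hide turnover: 6 calls were lost and 3 gained without the 2 libraries, 9 and 8 without the 4, and 3 and 6 with the block in the arsenic groups. Members of a list that vary together widen that test by construction. The detoxification list in mock turned from higher to lower without the 4 libraries (camera adjusted p 0.404). Of these, wild-type mock 1 and 4 had list means of 4.91 and 4.90 log2 CPM. The means were 5.41 and 5.38 in wild-type mock 2 and 3 and 5.31 to 5.54 in gl2-5 mock. The difference in mock thus rested on these 2 wild-type libraries, and why they were low was not tested. In the interaction this list became more positive in gl2-5 without the 2 and the 4 libraries (adjusted p 6.03e-05 and 6.12e-10, from 0.0769), so that its result rests on those libraries.

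Of 122 named results with a call, 94 kept it under every alternative run for them, and none turned direction; the 7 interaction values without a call gained one with DESeq2 and 5 of them with the block in the arsenic groups. The test against a 1.5-fold change ended the calls of the remaining 28. Replicate numbers were taken to pair the 2 arsenic groups and no other groups: all 4 of their same-number pairs had residual correlations over 0.1, against 1 of the others. Whether chance could give this was not tested. Between these 2 groups the highest r of libraries with different numbers was 0.134, but wild-type mock 1 and gl2-5 arsenic 2 reached 0.396. With the block in these groups 1393 genes differed in arsenic, and its changes of calls for that comparison and the interaction stand beside them; in the other comparisons it called hypoxia for arsenic in gl2-5 (0.0214) and proteasome in mock (0.0493) and ended the unfolded protein response in mock (0.0583), and it changed no other call of a list. The block in all groups called hypoxia for arsenic in gl2-5 (0.0191), jasmonate in mock (0.0406), and detoxification (0.0451) and hypoxia (0.0103) in the interaction, ended the call of TIP2 in mock (0.0501) and called AT5G25050 in the interaction (0.0457). Thinning to the smallest library left 12538, 12601, 538, 844 and 0 calls, and more depth was not tested. For the interaction, a 1.5-fold difference was recovered in 28.4% of simulated genes, so smaller differences in response were mostly not detectable.

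Among the 35 splits of the libraries of each pair of groups, the real split gave the most genes in all 4 comparisons, 1 of 35 each. Chance can be excluded at that share for arsenic in each genotype and for the genotypes in mock. It is the smallest share that 35 splits can give, and it is not adjusted for the number of comparisons. The splits ask about chance only, and not whether libraries high in green markers, such as wild-type mock 1 and 4, add to a count. The real splits gave 12762, 12348, 368 and 789 genes, and the highest of the others 0, 0, 7 and 0. If the arsenic groups are taken as paired by number, only the 8 splits that part every pair apply there, too few for a share under 0.05: the real one gave 789 and the others at most 0, or 2385 and at most 0 with the block. For the interaction the real count of 0 is reached by each of 100 splits drawn of 2450 by definition (highest 24), so this count says nothing on chance. Of the same splits 10 gave at least the real 2269 genes at an unadjusted p under 0.05 (highest 3004), but they ignore the pairs. With the block, 9 of 100 splits drawn of the 560 that part every pair gave at least the real 20 genes (highest 2244), and 7 at least the real 2678 at an unadjusted p under 0.05 (highest 5280), so chance cannot be excluded. The 8 others that reached 20 were among 13 that keep or swap the genotypes of all arsenic pairs and so hold the genotype difference in arsenic; the highest of the remaining 86 was 1, a division made after the counts were seen.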

Other observations

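The suberin and triterpene cluster tests were written before the values of their genes were seen, after other suberin and cluster genes had been noticed among the largest differences; the fits of the suberin genes without the 4 libraries highest in green markers were chosen after the result was seen. Higher levels of the suberin genes RWP1 and GPAT5 in gl2-5 under arsenic led to the hypothesis that the suberin pathway as a whole is higher there. Of 13 further suberin genes, 13 were higher in gl2-5 under arsenic, with a median of 0.68 log2 units and a fry p of 8.34e-04 in limma. Over all genes 7 were called, and 9 when adjusted over the list alone. The fry test asks whether a set changed by itself, whereas camera, used for the gene lists, compares a list with all other genes. The fry p values here are unadjusted and no camera result is given for this set, so its support cannot be ranked against that of the lists. In this comparison fry gave p of 0.00218 for proteasome and 0.0226 for root hair. Their camera adjusted p with an estimated correlation was 0.406 and 0.487. The fatty acid hydroxylase gene CYP86B1 was higher by 1.36 ± 0.20 (SE, n = 4 and 4 libraries), the acyltransferase gene GPAT7 by 1.32 ± 0.28, the elongase genes KCS2 and KCS1 by 0.96 ± 0.18 and 0.85 ± 0.14, the transporter genes ABCG20 and ABCG2 by 0.68 ± 0.17 and 0.68 ± 0.14, and the reductase gene FAR5 by 0.63 ± 0.12. Without the 4 libraries highest in green markers 13 of 13 were still higher, 4 with a call (fry p 0.00832), and without each arsenic library in turn 12 or 13 were higher, with 6 or 7 calls and a fry p of 4.75e-04 to 0.00293. In mock the median was 0.35 (fry p 0.0341) with 1 gene called over all genes, ABCG2 (7 when adjusted over the list alone), and the difference between the conditions was not shown (median interaction 0.28, fry p 0.219, 0 called over all genes and 2 when adjusted over the list alone). A higher suberin programme in gl2-5 roots may thus hold in both conditions. As it was found and tested on the same libraries, it stays a hypothesis, and no chemistry of the roots was measured in these data. With arsenic against mock in wild type, the 13 further suberin genes went both ways. MYB41, KCS1, GPAT7, KCS2, FAR1 and ABCG2 rose with a call, MYB92 and LACS2 fell with a call, and the rest had none.

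A lower level of CYP705A5, an oxidation gene of the thalianol cluster, in gl2-5 mock led to a test of 4 other genes of the thalianol and marneral clusters. Of the 4, 3 were lower, THAS1 with a call (−0.89 ± 0.17, edgeR adjusted p 0.0109), with a fry p of 0.0695 and a median of −0.32, so a coordinated difference could not be shown, and 4 genes are too few to exclude it.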
